A study of Homo sapiens with 6 samples.

How the data were processed

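DRIP-seq was run on U2OS cells, an established human osteosarcoma line. DRIP-seq immunoprecipitates fragments of genomic DNA that hold RNA-DNA hybrids and sequences them. Per the labels' protocols, the samples went through a DRIP protocol, were purified, and were sequenced by a BGI ChIP-seq procedure. The 6 libraries fall into 3 conditions: control siRNA (siCTRL), siRNA against RTEL1 (siRTEL1), and siRNA against RTEL1 with a second treatment that the labels call APH and do not spell out (siRTEL1_APH). Each condition has 1 undigested library and 1 library labelled RNaseH, so each group holds 1 library. No library combines APH with control siRNA, so APH without the knockdown was not measured.

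The submitters' processing notes name BWA and the genome build hg19, without a version or a role for BWA. The peak caller, its threshold, any input control and any filter are not given in the sources used here. Each library came as 1 list of regions. As deposited, a region carries a start, an end, a number and the number of peaks it holds. All positions are multiples of 10 kb, a region with 1 peak is always 1 window of 10 kb, and listed regions lie at least 100 kb apart. The lists give no score, fold, p-value or read count, so depth and enrichment are unknown, signal height was not compared, and width took the place of a score where regions were ranked. The regions lie on 22 autosomes and the X chromosome, and coordinates are printed 1-based on hg19.

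Within a chromosome the region numbers follow position but skip values, so the lists used here hold part of the numbered regions. The missing numbers amount to 31.8% of all numbers in siCTRL, 26.2% in siCTRL_RNaseH, 28.1% in siRTEL1, 20.3% in siRTEL1_RNaseH, 32.4% in siRTEL1_APH and 25.6% in siRTEL1_APH_RNaseH. What left them out is not recorded. A region of list A without overlap in list B was therefore counted in 2 ways: without any overlap, and without overlap inside a gap of B whose region numbers are consecutive. The first count can include regions whose row is missing from B, and the second leaves out gaps where a number is missing. This second count, the total of listed and missing numbers, and windows known in every list (listed, or in a consecutively numbered gap) were chosen after seeing the data, as were the windows grouped by digestion and the leaving out of single lists.

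Lists were compared by overlap of at least 1 bp on the grid of 10 kb windows, in Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The window grid took the place of bedtools, which had been chosen first, and was not compared with it; every region is made of whole windows. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat regions as independent. Each share was set beside 1000 random placements of the same regions over the 3027 Mb between the start and the last listed position of each chromosome. Similarity of lists was the Jaccard index, the windows in both lists divided by the windows in either. With 1 library per group, no test between conditions was run. After seeing the data, digested and undigested libraries were paired by condition, and an exact 2-sided test over all sign changes of the 3 paired differences was run, whose smallest p is 0.25. The length listed in only 1 library of a pair was compared over sequence known in both, also after seeing the data, with intervals from 10000 resamplings of the 23 chromosomes, as were the rates of regions in consecutively numbered gaps, with exact intervals, each per Mb of that sequence unlisted in the other list. The overlap and numbering steps were tested on simulated data: of 600 rows removed from the siCTRL list of 2677, 600 were found unmatched. Of these, 300 were removed before numbering, and 243 of them were resolved as absent. None of the other 300, deleted after numbering, was called absent (0 wrongly called). The unmatched count and the 0 follow from how rows were removed, so they check the code only. A smaller share of numbers was deleted than the 20.3 to 32.4% missing from the real lists. The part of absent regions resolved there may therefore be lower than in the simulation.

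The share of covered length on each chromosome was set beside the random placements. After seeing the data, covered share per chromosome was also set against the number of protein-coding genes per Mb over 23 chromosomes, with 100000 permutations for Pearson's r and Spearman's rho, both 2-sided, and Benjamini-Hochberg adjustment over the 6 libraries. The gene counts, 19974 genes in all, came from a GRCh38.p14 gene table, and only the number of genes per chromosome was taken from it. Its positions were not used, because the regions are on hg19 (the last listed position on chromosome 1, 249210000, lies past the last gene end of that table, 248937099). Naming genes in regions, the 10 gene lists fixed before the data were examined, the RTEL1 locus, promoter and gene body shares, GC content, G-quadruplex motifs and centromere distance need an hg19 annotation or genome and were not analysed here.

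The regions named in the text follow a rule written before the data were examined: for each of the 6 comparisons, the 10 widest regions of 1 list without overlap in the other, in both directions, and the 10 widest stretches listed in all 6 libraries. Where no score is listed, the rule takes width. Stretches named for their consecutive numbers or by digestion were added after seeing the data. The alternatives tried were a minimum overlap of 50% of the shorter region, touching regions (within 1 kb) counted as shared, the wider 50% of each list, lists cut to equal length by width, removal of regions present in all 3 digested lists, and a common minimum width.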

Results

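DRIP-seq, a method to map RNA-DNA hybrids, was run on U2OS osteosarcoma cells under 3 conditions. These were control siRNA (siCTRL), siRNA against RTEL1 (siRTEL1), and siRNA against RTEL1 with the treatment labelled APH (siRTEL1_APH). RTEL1 is a DNA helicase known for its work at telomeres and replication forks. Each condition had 1 undigested library and 1 library treated with RNase H, an enzyme that degrades the RNA strand of RNA-DNA hybrids. The digested library serves as the background of each condition. There were no replicates, so no difference between conditions has a replicate check, and read depth is unknown because the lists give regions without read counts. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. The RTEL1 locus was not analysed here, for lack of an annotation on the same build.

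The undigested lists held 2677 regions in siCTRL, 2939 in siRTEL1 and 2626 in siRTEL1_APH. The digested lists held 3083, 3533 and 3163 regions in the same order. The number of peaks within listed regions was 16226 in siCTRL, 16480 in siRTEL1 and 15854 in siRTEL1_APH, and 16932, 18867 and 16952 in their digests. Paired by condition, the digest listed more regions in 3 of 3 pairs, by 406, 594 and 537 regions (exact 2-sided permutation p = 0.25, the smallest that 3 pairs can give). With missing region numbers counted, the excess was smaller, at 249, 348 and 368 in the same order. Listed regions covered between 1115 Mb (36.8% of the span, siRTEL1) and 1261 Mb (41.7%, siRTEL1_RNaseH) of hg19. Covered length counts whole regions, and the lists do not place peaks inside them. Regions wider than a single window held between 12.97 (siRTEL1_APH) and 13.78 (siRTEL1_RNaseH) peaks per Mb. If every peak fills a single window, as in regions with a single peak, most of the covered length lies between peaks. The same limit holds for widths, shared lengths, the Jaccard index and the overlap of wider regions. Widths were very uneven. Single windows of 10 kb made up between 47.7% (siRTEL1_APH) and 50.6% (siRTEL1) of the regions, and the widest region in each list spanned 22.37 Mb. Between 20.3% and 32.4% of the region numbers were missing from the lists used here, so each count is a lower bound on the numbered regions.

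**Figure D1:**
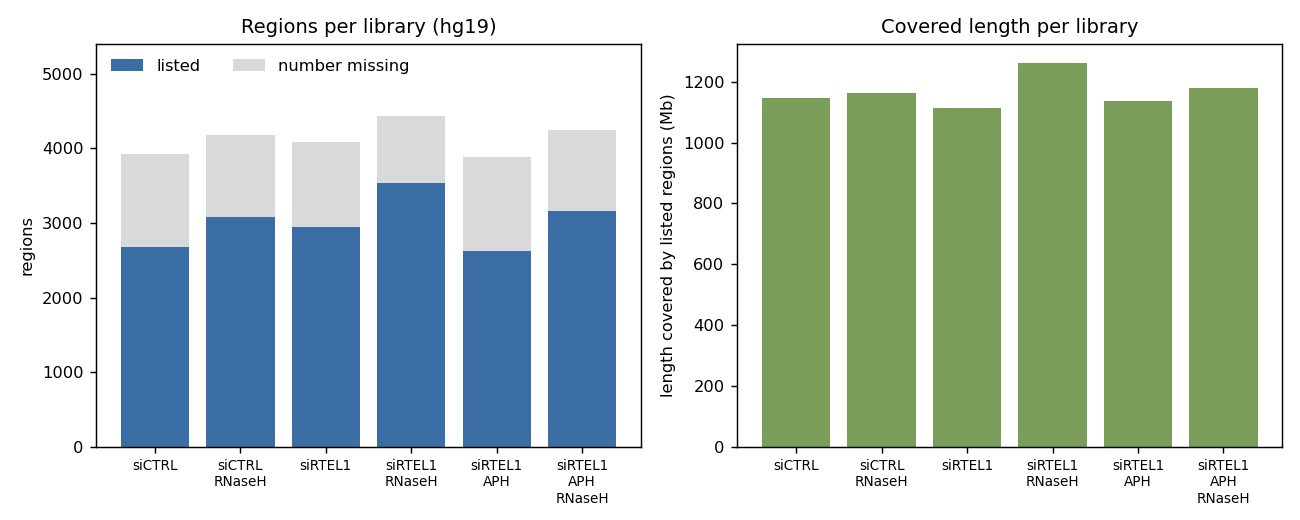
Left, regions per library, with listed regions in blue and missing region numbers stacked in grey, and right, the length in Mb covered by listed regions, each bar being 1 library without replicates. In each condition the RNase H library listed more regions than the undigested one, 3083 against 2677, 3533 against 2939 and 3163 against 2626.

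The 6 libraries listed much of the same sequence. Merging all lists gave 4147 regions, of which 1508 (36.4%, 95% interval 34.9 to 37.8%) held regions of all 6 libraries. By length the overlap was larger, and 881 Mb of the 1478 Mb listed in any library was listed in all 6 (59.6%). These lengths include sequence between the peaks of a region. The widest shared stretch ran over 22.37 Mb of chromosome 22 (28780001-51150000), up to the last listed window of that chromosome. It was followed by chromosome 16 (76960001-90120000, 13.16 Mb), chromosome 17 (70140001-81140000, 11 Mb), chromosome 3 (51210001-60170000, 8.96 Mb) and chromosome 19 (290001-8840000, 8.55 Mb). The remaining 5 of the 10 widest lay on chromosome 20 (29970001-38240000), chromosome 9 (133300001-141010000), chromosome 2 (234700001-242220000), chromosome 19 again (45020001-52410000) and chromosome 3 again (8390001-15700000), each between 7.31 and 8.27 Mb wide. Of the 1227 merged regions found in 1 library alone, 529 were in siRTEL1_RNaseH, the list with the fewest missing numbers.

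Coverage differed more between chromosomes than between libraries, as in the plot of covered share by gene density. Chromosome 19 was covered over 79.6% of its span on average over the 6 libraries (range 78.2 to 80.7%), chromosome 20 over 67.2%, chromosome 16 over 63.6% and chromosome 22 over 60.8%. The lowest shares were 17.02% on chromosome 13 (15.0 to 19.9%), 18.9% on chromosome 4 and 25.3% on the X chromosome. Chromosome 19 held more of the covered length than the 95% range of random placement in each of the 6 libraries (in siCTRL 4.14%, against 0.759 to 3.69%). Chromosomes 13 and 4 held less in each of the 6 (in siCTRL 1.64%, against 2.16 to 6.19%, and 3.08%, against 3.91 to 9.63%). The first 100 kb of a chromosome held a listed region on 2 of 23 chromosomes in siCTRL, 4 in siRTEL1 and 2 in siRTEL1_APH, and on 2, 3 and 3 in their digests. Chromosome 17 counted in siRTEL1 alone, and every other list has a missing number in the gap at its start. Chromosomes with more protein-coding genes per Mb were covered more in each library. Across 23 chromosomes Pearson's r lay between 0.748 (siRTEL1_RNaseH) and 0.818 (siRTEL1), and Spearman's rho between 0.714 (siCTRL_RNaseH) and 0.778 (siRTEL1). The largest permutation p over the 6 libraries was 0.0002 for rho (Benjamini-Hochberg adjusted 0.0002 over 6 libraries) and 2e-05 for r (adjusted 2e-05). Without chromosomes 19 and 17, the 2 farthest from the median gene density, r was 0.759 to 0.789. Chromosomes are not independent replicates. Over known windows alone rho fell to between 0.501 (siCTRL, permutation p = 0.02) and 0.645 (siRTEL1_RNaseH, permutation p = 0.001).

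**Figure D2:**
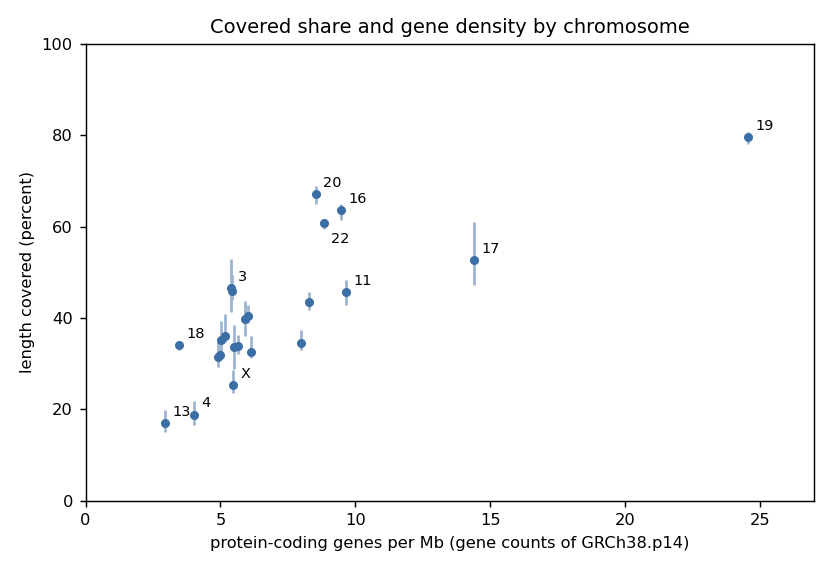
Share of each chromosome's span covered by listed regions (percent, vertical axis) against protein-coding genes per Mb (horizontal axis). Points are means over the 6 libraries and bars run from the lowest to the highest library, with chromosome 19 highest at 79.6% and chromosome 13 lowest at 17.02%. The span runs from the chromosome start and includes stretches where no library listed a region.

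In siCTRL most undigested regions overlapped a region listed after RNase H. Of 2677 undigested regions, 507 (18.9%, 95% interval 17.5 to 20.5%) had no overlap in siCTRL_RNaseH, against 47.4% for randomly placed regions. In the other direction, 845 of 3083 digested regions (27.4%, 25.8 to 29.0%) had no overlap in siCTRL, against 49.7% at random. Single windows made up 94.5% of the 507 regions, and only 28 of 1351 wider regions (2.07%) were absent after digestion. The widest undigested regions absent from the digest, apart from a stretch of chromosome 17 described with that chromosome, lay on chromosome 9 (89710001-90250000), chromosome 1 (219950001-220230000), chromosome 9 (89190001-89460000) and chromosome 5 (90420001-90640000). Only the last of these 4 fell where the digested list's numbers were consecutive. The widest in the reverse direction were on chromosome 5 (42920001-43610000, 9 peaks), chromosome 3 (98910001-99540000, 6 peaks) and chromosome 14 (39450001-39740000, 2 peaks), all 3 in gaps with a missing number. Counting only gaps with consecutive numbers, 172 undigested regions (6.43%, 5.53 to 7.42%) and 221 digested regions (7.17%, 6.28 to 8.14%) were absent from the other list. Per Mb of sequence known in both lists and unlisted in the other list, which is the denominator of each rate given here, the digested rate was 1.28 times the undigested one (exact 95% interval 1.05 to 1.58). Among the wider 50% of each list the absent shares were 10.2% and 18.2%, and with both lists cut to 2677 regions by width their order turned (25.3% undigested, 23.5% digested), a cut that drops narrow regions from the longer list alone.

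The gap between directions was widest in siRTEL1. Of 2939 undigested regions, 481 (16.4%, 15.0 to 17.8%) had no overlap in the digest, whereas 1255 of 3533 digested regions (35.5%, 33.9 to 37.1%) had none in the undigested list. Random placement gave 44.1% and 50.3%. Of the 1722 single windows in the digest, 62.1% had no overlap in the undigested list, against 10.3% of its 1811 wider regions. The share for single windows is close to the part of the span that siRTEL1 leaves uncovered, as it covers 36.8%. Against random placement, the lower pooled share therefore rests on wider regions. That yardstick lets windows fall anywhere, whereas single windows lie at least 100 kb from any other region of their own list. Most of the length siRTEL1 covers lay in regions of the digest (1014 Mb, against 101 Mb outside them). Whether single windows overlapped more often than chance therefore cannot be told from this share. With consecutive numbers only, the counts were 239 (8.13%, 7.17 to 9.18%) and 397 (11.2%, 10.2 to 12.3%), and the digested rate per Mb of known sequence unlisted in the other list was 1.49 times the undigested one (1.26 to 1.75). In sequence known in both lists, 153 Mb was listed after digestion alone and 76.2 Mb without digestion alone, whereas these lengths were 82.2 and 82.1 Mb in siCTRL and 100.6 and 99.2 Mb in siRTEL1_APH. Beyond chromosome 17, the widest undigested regions absent from the digest lay on the X chromosome (114900001-115200000), chromosome 16 (7190001-7480000) and chromosome 20 (21020001-21220000, consecutive numbers). The widest digested regions absent from the undigested list lay on chromosome 13 (112580001-114260000, 20 peaks), chromosome 3 (98910001-99540000, 5 peaks), chromosome 3 (26570001-27140000, 5 peaks), chromosome 2 (169250001-169810000, 4 peaks) and the X chromosome (146820001-147320000, 6 peaks), and of the 10 widest 1, on chromosome 8 (86840001-87310000), fell in consecutive numbers. Among the wider 50% of each list, 8.92% of undigested and 28.8% of digested regions were absent from the other.

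In siRTEL1_APH, 490 of 2626 undigested regions (18.7%, 17.2 to 20.2%) had no overlap in the digest, and 947 of 3163 digested regions (29.9%, 28.3 to 31.6%) had none in the undigested list. Random placement gave 46.3% and 49.9%. The widest undigested regions absent after digestion lay on chromosome 15 (61180001-61480000), chromosome 8 (12730001-12940000), chromosome 10 (95030001-95220000), chromosome 3 (111620001-111810000) and chromosome 7 (133750001-133900000), each with 2 peaks and all but the one on chromosome 8 in consecutive numbers. The widest in the reverse direction were on chromosome 9 (130190001-132980000, 47 peaks, and 89190001-91660000, 25 peaks), where a number was missing from the undigested list. With consecutive numbers only, the counts were 181 (6.89%, 5.95 to 7.93%) and 228 (7.21%, 6.33 to 8.17%), and the digested rate per Mb of known sequence unlisted in the other list was 1.26 times the undigested one (1.03 to 1.54). Among the wider 50% of each list, 10.9% of undigested and 20.9% of digested regions were absent from the other, and at equal list length the order turned as in siCTRL (26.5% and 24.7%). Without regions present in all 3 digested lists, the 12 shares of the 6 comparisons in both directions lay between 44.2 and 73.2%.

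**Figure D3:**
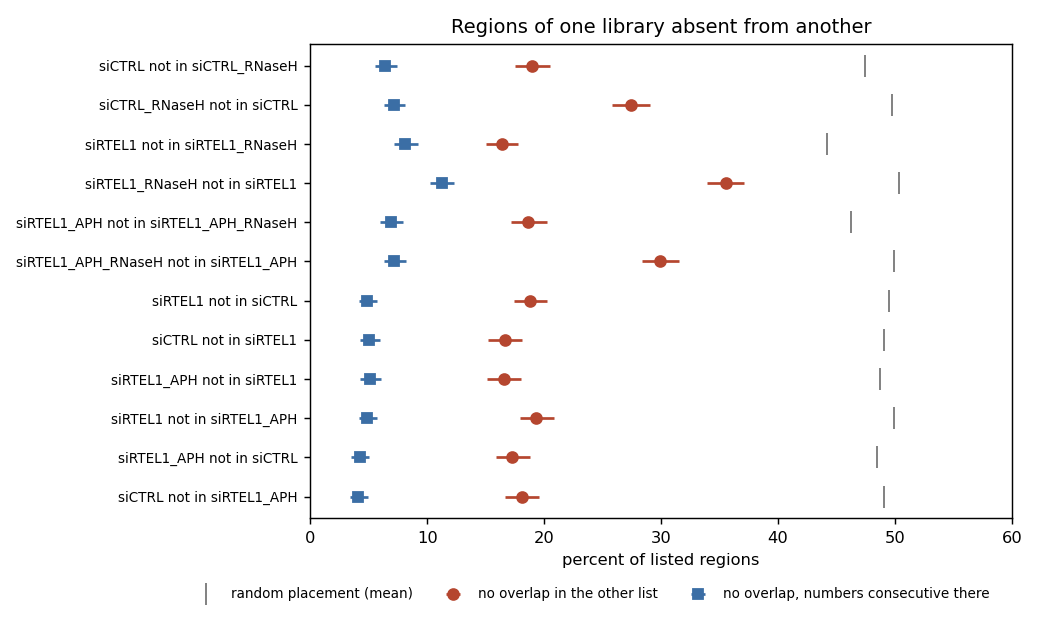
Percent of the listed regions of 1 library with no overlap in another, for each of the 6 comparisons in both directions. Red circles count every region without overlap and blue squares only those in gaps with consecutive region numbers, both with exact 95% intervals, grey ticks are means of 1000 random placements, and the RNase H libraries stand at 27.4, 35.5 and 29.9% absent from their undigested partners, and every other red circle lies between 16.4 and 19.3%.

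The lists were also compared by digestion across conditions. The Jaccard index was 0.824 to 0.833 between undigested lists, 0.797 to 0.809 between digested lists, and 0.745 to 0.813 between a digested and an undigested list. There were 849 windows in all 3 undigested lists and in no digested list, in 139 stretches. In 516 of these windows the numbers settle presence or absence in all 6 lists. The widest stretches of these were on chromosome 12 (7030001-7280000), chromosome 1 (8670001-8900000), chromosome 22 (22350001-22580000), chromosome 8 (22860001-23080000) and chromosome 14 (35610001-35810000). The opposite pattern, all 3 digested lists and no undigested one, held 2427 windows in 454 stretches, of which 942 windows were known in all 6. The widest of these lay on chromosome 7 (38600001-38990000), the X chromosome (63010001-63390000), chromosome 9 (104030001-104400000 and 112650001-112940000) and chromosome 4 (55240001-55510000). These stretches were chosen after their values were seen. Without the siRTEL1 pair of libraries, the counts were 2728 and 4235 windows.

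RTEL1 knockdown was compared with control siRNA to ask where regions appear or disappear. The lists hold no measure of RTEL1 RNA or protein, so depletion of the helicase was not checked here. Of 2939 siRTEL1 regions, 553 (18.8%, 17.4 to 20.3%) had no overlap in siCTRL, and 445 of 2677 siCTRL regions (16.6%, 15.2 to 18.1%) had none in siRTEL1. Random placement gave 49.5% and 49.0%. Single windows made up 92.4% and 93.9% of these. Apart from chromosome 17, the widest regions of siRTEL1 alone lay on chromosome 5 (42990001-43610000, 8 peaks), chromosome 15 (61180001-61530000, 2 peaks, consecutive numbers), chromosome 3 (181330001-181600000, 3 peaks) and chromosome 9 (1860001-2080000, 3 peaks). The siCTRL_RNaseH list holds regions that overlap those on chromosome 5 (42920001-43610000) and chromosome 15 (61130001-61270000). The widest of siCTRL alone lay on chromosome 9 (89710001-90250000, 4 peaks), chromosome 6 (154470001-154960000, 2 peaks) and chromosome 16 (13790001-14090000, 2 peaks, consecutive numbers). With consecutive numbers only, the 2 directions gave 144 regions (4.90%, 4.15 to 5.74%) and 135 regions (5.04%, 4.24 to 5.94%), so the order of the shares turned, with overlapping intervals. It turned at equal list length too (16.997% and 21.96%), and per Mb of known sequence unlisted in the other list, the siRTEL1 rate was 1.12 times the siCTRL rate (0.881 to 1.43).

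RNase H-sensitive regions, those without overlap in the digest of their own condition, were compared in the same way. The name states only this definition. Undigested regions absent from their own digest made up 16.4 to 18.9% of each list, much as between undigested lists (16.5 to 19.3%). In each condition more regions were listed in the digest alone than in the undigested list alone. Of the 481 in siRTEL1, 265 (55.1%, 50.5 to 59.6%) had no overlap in the undigested siCTRL list, and of the 507 in siCTRL, 267 (52.7%, 48.2 to 57.1%) had none in siRTEL1. These sets were chosen for absence from 1 list, and single windows made up 92.9% and 94.5% of them. Among all single windows, 34.4% of those in siRTEL1 were absent from siCTRL and 31.5% the other way. The shares therefore cannot show that a region is particular to a condition. Where the other undigested list's numbers were consecutive, 79 of the 481 and 79 of the 507 were absent from it. Of the 507 in siCTRL, 38 were also sensitive in both other conditions, and 2 of 172 when numbers had to be consecutive. The number that chance would give was not computed, so these counts cannot be called low or high. The widest of the 38 was on chromosome 15 (71070001-71150000, 2 peaks). Covered length in siRTEL1 minus siCTRL was -31.2 Mb without digestion (1115 and 1146.5 Mb) and 99.1 Mb after it (1261 and 1162 Mb). Missing rows affect these lengths, and siRTEL1_RNaseH had the fewest missing numbers. In sequence known in both lists of a condition, the digest alone listed 153 Mb in siRTEL1 and the undigested list alone 76.2 Mb. In siCTRL these lengths were 82.2 and 82.1 Mb.

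With APH added to the knockdown, fewer regions were listed, 2626 against 2939, while the covered length was 1138 against 1115 Mb. Listed plus missing numbers came to 3882 against 4086. Of the siRTEL1_APH regions, 434 (16.5%, 15.1 to 18.004%) had no overlap in siRTEL1, and 568 siRTEL1 regions (19.3%, 17.9 to 20.8%) had none in siRTEL1_APH. Random placement gave 48.7% and 49.9%. The widest regions of siRTEL1_APH alone lay on chromosome 16 (13660001-14090000, 3 peaks), chromosome 14 (51220001-51440000, 2 peaks), chromosome 8 (12730001-12940000, 2 peaks) and chromosome 7 (14230001-14420000, 3 peaks), the first 2 in consecutive numbers. The widest of siRTEL1 alone with consecutive numbers were on the X chromosome (114900001-115200000, 2 peaks) and chromosome 8 (98120001-98290000, 2 peaks), and wider ones on chromosomes 17, 9 and 13 fell where a number was missing. Among RNase H-sensitive regions, 251 of 490 in siRTEL1_APH (51.2%, 46.7 to 55.7%) had no overlap in siRTEL1, and 263 of 481 the other way (54.7%, 50.1 to 59.2%), of which 85 and 75 lay where the other list's numbers were consecutive. Among all single windows, 31.7% of those in siRTEL1_APH were absent from siRTEL1 and 35.5% the other way. The limit given above for sets chosen by absence holds here too. Over all regions, with consecutive numbers only, the 2 directions gave 134 regions (5.10%, 4.29 to 6.01%) and 144 regions (4.90%, 4.15 to 5.74%). The order of the shares turned, with overlapping intervals, as it did at equal list length (22.96% and 17.02%), and the siRTEL1_APH rate per Mb of known sequence unlisted in the other list was 0.883 times the siRTEL1 rate (0.693 to 1.13).

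The siRTEL1_APH and siCTRL libraries differ in both knockdown and APH, so the 2 treatments cannot be separated in this comparison. Of 2626 siRTEL1_APH regions, 454 (17.3%, 15.9 to 18.8%) had no overlap in siCTRL, and 484 of 2677 siCTRL regions (18.1%, 16.6 to 19.6%) had none in siRTEL1_APH. Random placement gave 48.5% and 49.1%. The widest regions of siRTEL1_APH alone were on chromosome 5 (42990001-43610000, 8 peaks) and chromosome 15 (61180001-61480000, 2 peaks). Both also appear among siRTEL1 regions absent from siCTRL, a comparison with the same siCTRL list. A region number is missing from siCTRL at the chromosome 5 stretch, and siCTRL_RNaseH lists it (42920001-43610000, 9 peaks). The siCTRL_RNaseH list also holds a region that overlaps the chromosome 15 stretch (61130001-61270000, 3 peaks). The widest of siCTRL alone, after chromosomes 17 and 9, lay on chromosome 1 (101690001-101910000, 3 peaks), chromosome 6 (167710001-167920000, 4 peaks) and chromosome 19 (20070001-20270000, 3 peaks, consecutive numbers). Among RNase H-sensitive regions, 253 of 490 (51.6%, 47.1 to 56.1%) and 282 of 507 (55.6%, 51.2 to 60.001%) had no overlap in the other undigested list, of which 66 and 68 lay where its numbers were consecutive. Among all single windows these shares were 33.3% in siRTEL1_APH and 33.9% in siCTRL, and the same limit holds. Over all regions, with consecutive numbers only, 111 regions (4.23%, 3.49 to 5.07%) and 110 regions (4.11%, 3.39 to 4.93%) were absent. The order of the shares turned, with overlapping intervals, as it did at equal list length (18.3% and 17.6%), and the ratio of the rates per Mb of known sequence unlisted in the other list was 1.009 (0.768 to 1.33).

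The widest regions that differed between lists lay on chromosomes 17 and 9. A region of 6970 kb with 110 peaks (chromosome 17, 3420001-10390000) was listed in siCTRL, and nearly the same stretch (3450001-10240000, 105 peaks) in siRTEL1, where a further region (470001-3290000, 46 peaks) came before it. Neither stretch was listed in siRTEL1_APH or in any digested list. On chromosome 9, a region of 4230 kb (128740001-132970000, 72 peaks in siRTEL1) was covered in part or in full in each list except siRTEL1_APH. In each list that lacked one of these 3 stretches, a region number was missing there, so they cannot be read as lost in those libraries.

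**Figure D4:**
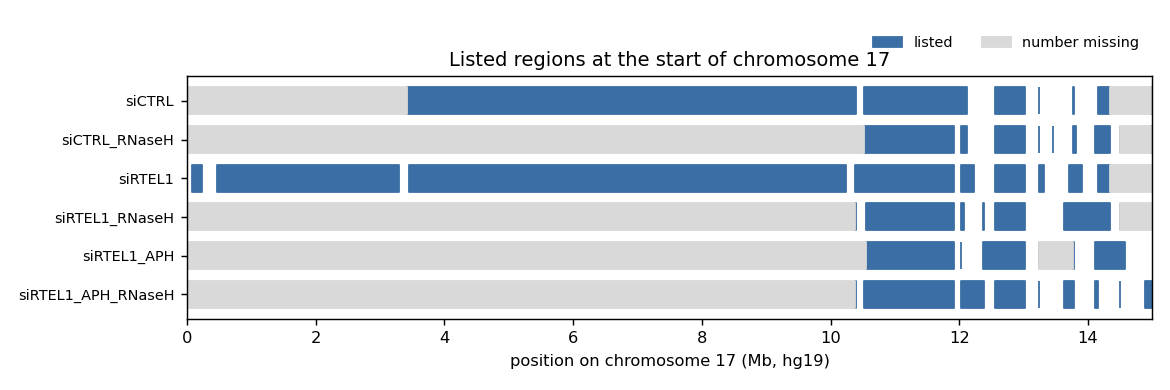
Listed regions (blue) over the first 15 Mb of chromosome 17 (horizontal axis, Mb on hg19) in the 6 libraries, with gaps where a region number is missing in grey and gaps with consecutive numbers in white. The stretch from 3450001 to 10240000 is listed in siCTRL and siRTEL1 and grey in the other 4 libraries.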

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

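The tests in this part were chosen after the data had been seen, and only for windows known in all 6 lists was the limit set before the count was made.

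Several contrasts went one way without RNase H and the other way with it, and none of these differences was tested, since each group holds 1 library. Covered length in siRTEL1 minus siCTRL was -31.23 Mb undigested and 99.06 Mb digested, a difference of -130.29 Mb. For siRTEL1_APH minus siRTEL1 it was 23.13 Mb undigested and -81.15 Mb digested, a difference of 104 Mb. For siRTEL1_APH minus siCTRL it was -8.1 Mb and 17.91 Mb, a difference of -26.01 Mb. The same contrast gave -51 and 80 listed regions (difference -131), -44 and 75 listed plus missing numbers (difference -119), and -372 and 20 peaks (difference -392). Missing rows affect the covered lengths. In sequence known in both lists of a condition, the digest alone listed 82.24 Mb in siCTRL, 152.96 Mb in siRTEL1 and 100.6 Mb in siRTEL1_APH. The undigested list alone held 82.08, 76.23 and 99.17 Mb. The size of the covered-length contrasts therefore depends in part on missing rows. Median region width in siRTEL1 minus siCTRL was -30 kb undigested and 30 kb digested, a difference of -60 kb. Digested minus undigested, it was -30 kb in siCTRL, 30 kb in siRTEL1 and -10 kb in siRTEL1_APH, so siRTEL1 differed from siCTRL (-60 kb) and from siRTEL1_APH (40 kb). Single windows made up 47.7 to 50.6% of each list, and the median jumps from 10 kb to 40 kb or more as that share passes below 50%, so these width differences rest on small shifts in it.

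More regions were listed after RNase H in all 3 conditions. Missing region numbers do not account for this alone, since listed plus missing numbers were at least 1.06 times higher in each digest, and the lowest digested total (4175) exceeded the highest undigested one even with the most regions that could follow the last listed ones (4100). Cutting of the same length into more regions is argued against in siRTEL1 alone, where the length listed after digestion alone was 2.01 times that listed without it alone, in sequence known in both lists (95% interval 1.68 to 2.41, chromosomes resampled); in siCTRL and siRTEL1_APH the ratios were 1.002 (0.849 to 1.18) and 1.014 (0.849 to 1.215), so cutting stays open there, although the rate of regions in consecutively numbered gaps was higher after digestion in each condition (lowest ratio 1.26, 1.03 to 1.54). The biological reading that RNA-DNA hybrids gave most listed regions and the digest removed them fully was set against the share absent from the digest. At most 18.9% of undigested regions were absent, where the 95% ranges of random placement began at 42.5% or higher. Random placement replaced a limit of 50% as the yardstick after the values were seen, and the share lies below either. These shares argue against the loss of most listed regions as a whole. They do not show that the peaks stayed, since 1 shared window counts a wider region as present and the lists do not place peaks. Single windows alone were absent in 36.1% (siCTRL), 30.1% (siRTEL1) and 35.4% (siRTEL1_APH). Random placement also reaches sequence that no list covers, so it is a loose yardstick. A partial digest, lower signal inside regions that stayed listed, and depth or enrichment stay open, because the lists hold no read counts.

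Windows listed in all 3 digested lists alone or all 3 undigested lists alone numbered 3276. Of the 10 splits of the 6 lists, 1 (the real one) gave as many, and the highest of the others gave 1014; 10 splits are too few for a share under 0.05. Missing region numbers do not account for the pattern, since among windows known in all 6 lists the real split gave 1458 and the highest other 508. The biological explanation, that RNase H shifts the same places in each condition, stays open, as does a shared difference in depth or library preparation between digested and undigested libraries, which coincides with digestion.

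The megabase stretches of chromosomes 17 and 9 looked like losses in up to 5 libraries. Missing region numbers could account for this: in 10 of 10 cases where a list left a stretch uncovered, a number was missing there. A real loss in one of these libraries was neither shown nor excluded by the lists used here.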

How the results depend on the processing

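The alternatives for missing region numbers, for windows known in all 6 lists and for lists left out were chosen after seeing the data; the others were set before the data were examined. No paired analysis was possible by replicate number, because each group holds 1 library. Pairing digested with undigested libraries by condition gives 3 pairs and no p under 0.25. Removing mitochondrial and contig regions removed nothing, the alternative placement within a region's own chromosome cannot move chromosome shares, and the alternatives for promoters and gene lists were not run, as no hg19 annotation was used here. Without read counts, depth limits every count in a way that is not known.

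Shares absent from the other list are given for the RNase H comparisons in siCTRL, siRTEL1 and siRTEL1_APH, then siRTEL1 against siCTRL, siRTEL1_APH against siRTEL1 and siRTEL1_APH against siCTRL, each followed by its reverse. Every share changed beyond its counting interval under 3 settings. With consecutive region numbers required they were 6.43, 7.17, 8.13, 11.2, 6.89, 7.21, 4.90, 5.04, 5.10, 4.90, 4.23 and 4.11%. Among the wider 50% of each list they were 10.2, 18.2, 8.92, 28.8, 10.9, 20.9, 13.2, 12.03, 11.4, 13.8, 12.3 and 13.005%. Without regions present in all 3 digested lists they were 63.9, 64.2, 53.2, 73.2, 63.6, 70.6, 49.6, 44.96, 44.2, 49.004, 46.2 and 47.2%. These settings drop gaps, narrow regions or shared regions by construction. With consecutive numbers the order of a share and its reverse turned in the 3 comparisons between conditions.

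With lists made equally long they were 25.3, 23.5, 22.7, 29.4, 26.5, 24.7, 16.997, 21.96, 22.96, 17.02, 18.3 and 17.6%, of which those for siRTEL1_APH against siCTRL stayed inside their intervals. The order of a share and its reverse turned in 5 of the 6 comparisons, all but the RNase H comparison in siRTEL1. The setting drops narrow regions from the longer list alone, and most unshared regions are single windows, so by construction it lowers the longer list's share and raises the other. With regions within 1 kb counted as shared they were 16.997, 25.7, 14.5, 34.1, 16.9, 28.5, 17.3, 15.02, 14.9, 17.8, 15.8 and 16.6%, of which 2, the reverse shares of the RNase H comparisons in siRTEL1 and siRTEL1_APH, stayed inside. Requiring overlap of 50% of the shorter region left 9 shares inside their intervals and gave 17.999, 20.3 and 32.1% for the RNase H comparison in siRTEL1, that in siRTEL1_APH and its reverse.

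With a minimum width of 40 kb, the siCTRL median, the lists held 1348 (siCTRL), 1527 (siCTRL_RNaseH), 1450 (siRTEL1), 1809 (siRTEL1_RNaseH), 1368 (siRTEL1_APH), 1629 (siRTEL1_APH_RNaseH) regions, fewer by construction. Listed plus missing numbers (3882 to 4434) stayed within 1.5 times the listed counts in all 6 libraries. Merged regions in all lists came to 38.4% with regions within 1 kb merged, 47.4% in the wider 50% and 41.0% without the siRTEL1_RNaseH list. Windows in all lists came to 59.98% in the wider 50% and 63.7% without that list. Windows in the 3 undigested lists alone fell to 516 when known in all 6 lists and rose to 2728 without the siRTEL1 pair, and those in the 3 digested lists alone went to 942 and 4235. Fewer lists to satisfy explains the higher counts by construction, and the cause of the other changes was not tested.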

Other observations

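The tests in this part on distal chromosome ends were chosen after the widest shared stretches had been seen, and the finer classes of gap length were added after a first result. The comparison with other bins of 5 Mb replaced one with the rest of the chromosome, which had given a higher distal share in 22 or 23 of 23 chromosomes per list.

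The ends of the long arms were covered more than the mean of the other bins on most chromosomes in each of the 6 libraries. Single bins elsewhere were often covered more, and only on chromosomes 2, 9 and 22 was no other bin covered more than the distal one in all 6 lists. The outermost 5 Mb before the last listed window was covered over 78.6% on average across 23 chromosomes in siCTRL, 76.1% in siRTEL1 and 78.8% in siRTEL1_APH, against 41.8, 40.8 and 41.4% in the other bins of 5 Mb that held a region of any list. The digested lists gave 77.9, 80.0 and 76.4% against 41.9, 44.8 and 42.5%. Chromosome 22 was covered over 100% of its outermost 5 Mb, chromosome 17 over 99.9%, chromosome 9 over 99.9%, chromosome 16 over 99.5% and chromosome 2 over 99.3% (means over the 6 libraries), while chromosome 4 reached 35.5%. The distal share was the higher one in 21 chromosomes in siRTEL1_RNaseH (exact sign test, 2-sided p = 6.6e-05), in 22 in both other digests (p = 5.7e-06) and in 23 in the undigested lists (p = 2.4e-07). The exceptions were on chromosomes 1 and 19. These values met the prediction that the outermost 5 Mb of the long arms is covered more than the other bins on average. The distal bin ends at the last window that any list holds, and the other bins are not anchored on a listed region. This favours the distal bin by an amount that was not measured. The sign test also treats chromosomes as independent, which they are not. The higher share was there in digested lists too, and it may reflect gene density or base composition, which were not tested within chromosomes.

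Missing region numbers fell in the same sequence of the 6 lists more than when shuffled among gaps of like length. Gaps with a missing number in all 6 lists covered 192.68 Mb, against 80.4 Mb on average (95% range 53.8 to 115 Mb) when missing numbers were shuffled among 200 classes of like gap length, and 86.8 Mb with 20 classes (permutation p = 0.001 in both, the smallest that 1000 permutations can give). Of the gaps with a missing number, 89.6% on average over the 6 lists held a region of another list, against 83.6% after shuffling (permutation p = 0.001 in each list, the smallest possible). Both hypotheses were formed after single stretches of this kind had been seen. The first result met the prediction of the hypothesis that missing numbers recur at the same positions in the 6 lists. The second met that of the hypothesis that they mark places where other lists hold regions. However, a missing number marks a numbered region left out of the list, while a consecutive gap held none. Since the lists share many regions, a higher share follows from the numbering itself. In the first test, shuffling treats gaps of like length as exchangeable, so recurrence can also follow from the regions that the lists share. Neither test can therefore tell what left the rows out, or whether it acted at the same positions. 

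Among regions of 2 or more windows, absence from another list was rare in the undigested comparisons, at 1.9985 to 2.89% of wider regions, and ranged up to 10.3% for siRTEL1_RNaseH regions absent from siRTEL1. Among the digests, siRTEL1_RNaseH covered the most length (1261 Mb), listed the most peaks (18867), and 529 merged regions were in it alone, against 186 in siRTEL1_APH_RNaseH and 167 in siCTRL_RNaseH. It also had the fewest missing numbers (20.3%, against 25.6 and 26.2%), and its listed plus missing numbers (4434) were closer to those of the other digests (4250 and 4175) than its listed regions were (3533, against 3163 and 3083).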
